A study of Homo sapiens with 4 samples.

How the data were processed

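RNA from MCF10F mammary epithelial cells was made into libraries with a stranded mRNA kit and sequenced from both ends on an Illumina instrument, per the labels' protocols. The labels give 1 non-targeting control, 1 polyclonal and 2 clonal FUBP1 knockout libraries. Nothing in the labels says that libraries came from separate cultures. STAR 2.6, RSEM, Bowtie2 and the build hg38 were used, in roles not given in the sources used here, per the submitters' processing notes. The program behind the splicing tables is not among the tools taken from these notes.

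The 5 splicing tables hold the authors' counts of reads for the inclusion and the skipping form of each event, with the length of both forms, per the file headers and the deposited notes. The authors' inclusion level is a fraction, and the authors' p-value and FDR per event were also deposited. Each count cell holds 2 values, called replicates in the deposited notes. They are called count sets here, since the labels list 1 sample per side and what separates them is not given in the sources used here. They were summed for the comparison of libraries. Inclusion levels were recomputed as inclusion reads over form length divided by the sum of both forms, and differed from the deposited fraction by at most 0.0005. Inclusion stands for the exon in skipped exons, the longer exon at alternative splice sites, the retained intron, and for mutually exclusive exons the exon of lower coordinate on the plus strand and of higher coordinate on the minus strand.

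The gene and isoform tables hold the authors' comparison, per the file headers: posterior probabilities of equal and of different expression (a score between 0 and 1 for each gene), a posterior and a raw fold change as a ratio of condition 1 over condition 2, and the authors' normalized mean signal in each condition. The lowest posterior probability of different expression in the deposited tables was 0.99, so the planned threshold of 0.95 and the alternative of 0.99 take the same rows. The log2 fold changes printed here are the negative log2 of the authors' posterior ratio, so that positive values are higher in condition 2. Values of exactly 0 are given as listed at 0, without a fold. With only a comparison deposited, no test across libraries was run on genes or isoforms, as the plan fixed before the data were examined provides. The planned comparison of polyclonal with clonal knockouts and the fold changes per library were not analysed here for the same reason.

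Skipped exons and the other event types were each tested with a two-sided Fisher's exact test on summed reads, at a minimum of 20 counts in each library, with Benjamini-Hochberg adjustment per type, and called at an adjusted p under 0.05 and a difference of at least 0.1. Count sets of a library were compared in the same way at a minimum of 10 counts in each. An exon with other neighbors is a separate event, so counts of skipped exons are counts of events. Intervals are Wilson intervals at 95% of the read share, carried over to the inclusion level. The same interval is used where a form had 0 reads. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. In simulated data for 17340 skipped exons with counting noise, 100 exons were changed by 15 percentage points and 100 by 30 points. The test found 30% and 88% of them, and called 2 unchanged exons. A second simulation gave every exon the same added spread, between the averages of inclusion (14.6) and skipping reads (9.65) of the polyclonal count sets. There the test called 881 unchanged exons of 16981 tested. Exons without skipping reads in the control could gain none in these simulations, and the spread seen varied with depth. These counts are therefore not a rate of false calls under the noise seen.

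A total of 26 gene lists were fixed before the data were examined, and gene names and coordinates were taken from GENCODE release 29 on the same build. Of the deposited gene identifiers 7997 of 8015 matched, and of the isoform identifiers 22623 of 22637. For expression, a list with at least 5 listed genes was described by the median of its log2 fold changes and the percentile of that median among 10000 random lists matched by decile of mean expression. The random lists were drawn from the genes of the authors' deposited table, all with a posterior probability of at least 0.99. Counts, medians and percentiles of the lists thus hold among listed genes only. For splicing, genes with a called skipped exon were compared with other tested genes by a two-sided Fisher's exact test for each of 21 lists, with a logistic model as the alternative. The labelled level of a gene is the log2 ratio of polyclonal to control reads on the exon with the most inclusion reads (at least 100 over both libraries, 0.5 added to each), with the median over 6132 genes (-0.32) removed.

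The rule for named genes was fixed before the data were examined: FUBP1, the 8 genes with the highest and the 8 with the lowest log2 fold change at a mean of at least 100 in the higher condition, up to 4 members of each list by size of change, the 10 skipped exons with the largest difference at 50 or more counts in each library, 3 events of each other type, and 12 called events in tumor suppressors or oncogenes. Some of the results this rule names are not reported here. Alternatives were the authors' FDR, a beta-binomial test with an overdispersion of 0.01, minimum counts of 10 and 50, differences of 0.05 and 0.2, an absolute log2 fold change of 1, a mean of at least 100, any event type in place of skipped exons, and genes above the median of labelled reads. Those using the count sets were chosen after seeing the data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.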

Results

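RNA sequencing was used to ask what the loss of FUBP1 does to gene expression and splicing in MCF10F, a line of non-transformed human mammary epithelial cells. FUBP1, the far upstream element binding protein, binds single-stranded DNA and RNA and is known as a regulator of MYC transcription. The series holds 4 libraries: 1 non-targeting control, 1 polyclonal FUBP1 knockout and 2 clonal FUBP1 knockouts. The splicing tables cover the control and the polyclonal knockout, with 39597503 and 31043376 reads over skipped-exon events, where a read can count in several events. Each library's counts came as 2 count sets, which the file notes call replicates, and because the labels give 1 sample per side they were summed and counted as 1 library. The gene and isoform tables hold only the authors' comparison of a condition 1 with a condition 2, without values per library. The splicing comparison has 1 library per side, so its intervals cover counting error only and its tests on reads compare these libraries, not the conditions.

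The libraries behind conditions 1 and 2 are not given in the sources used here, so the direction of the authors' deposited table was read from the labelled splicing counts. Across 3550 genes, FUBP1 left out, the change from condition 1 to condition 2 in the authors' deposited table ran with the change in exon reads from the control to the polyclonal knockout (Spearman's rho 0.865, across genes, which are not independent replicates). Of the 1094 genes with an absolute log2 change of at least 1 in the authors' deposited table, 1063 moved the same way in the labelled reads. Condition 1 is called the control side below and condition 2 the knockout side. Which of the 3 knockout libraries entered the knockout side stays open. The labelled reads come from the only control library and from the polyclonal knockout, which may be part of the knockout side. Where they move like the authors' deposited table below, they are not independent support.

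FUBP1 RNA was reduced in the knockout. In the labelled counts, reads on the FUBP1 exon at chromosome 1, 77967627 to 77967666 (hg38, coding), fell from 1169 in the control to 147 in the polyclonal knockout, a log2 change of -2.66 after the median change of all genes was removed. Reads skipping this exon numbered 0 in the control (inclusion 100%, 95% Wilson interval 99.5 to 100) and 20 in the polyclonal knockout, where inclusion was 84.0% (76.8 to 89.3), with 100% and 75.7% in the count sets. In a second event with the same exon and other neighbors, inclusion went from 100% of 861 reads to 66.6% (59.2 to 73.2), with 48.9% and 88.5% in the count sets. The exon at 77968165 to 77968203 went from 727 to 204 inclusion reads. In contrast, reads on the exon at 77966884 to 77966955 went from 299 to 181, a log2 change of -0.40, and those on the longer form of the exon at 77967049 to 77967101 from 164 to 145 (log2 0.15). In the authors' deposited table, FUBP1 (ENSG00000162613) had a normalized mean of 3120 on the control side and 2023 on the knockout side, a log2 fold change of -0.62. Among its transcripts in the authors' deposited table, the nonsense-mediated decay transcript FUBP1-201 went from 1222 to 350, the coding FUBP1-203 from 1606 to 995 and the processed transcript FUBP1-211 from 265 to 442. The level of FUBP1 in each knockout clone was not analysed here. Of its relatives, PUF60 (log2 -0.73) and KHSRP (log2 -0.30), both RNA-binding proteins of the splicing machinery or mRNA decay, were also lower on the knockout side in the authors' deposited table.

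Gene expression differed broadly between the control side and the knockout side. The series holds 1 control library, so a trait of that library cannot be told apart from an effect of the loss of FUBP1. The authors' deposited table lists 8015 genes, of which 3632 were higher and 4383 lower on the knockout side, and 1631 and 2353 when an absolute log2 fold change of at least 1 was asked for. FABP4, a fatty acid carrier of adipocytes, was listed at 0 on the control side and at 741 on the knockout side in the authors' deposited table. NPR3 (241), ST6GALNAC3 (144), OASL (116) and the antisense RNA ZFPM2-AS1 (120) were likewise listed at 0 on the control side in the authors' deposited table. CCNA1, the germline cyclin A, went from 5.03 to 1093 (log2 7.62) and CHAC1, a glutathione-degrading enzyme induced by stress, from 2.09 to 463 (log2 7.37) in the authors' deposited table. AC012184.2 (log2 7.51) was the remaining one of the 8 highest genes in the authors' deposited table, and since it overlaps 2 genes on its strand its level is uncertain, as is that of ZFPM2-AS1, which overlaps 3. At the other end, the authors' deposited table lists at 0 on the knockout side TNFRSF11B, the decoy receptor osteoprotegerin (693 on the control side), CACNG4 (304), the chloride channel ANO1 (246), TMSB15B (246), MGC32805 (178), UGT8 (156) and REEP1 (150). ANO1, TMSB15B and UGT8 each overlap 1 gene on their strand, and TMSB15B has a near-identical copy, so their levels in the authors' deposited table are uncertain. HNRNPUL2-BSCL2, a readthrough locus that shares reads with its 2 neighbors, went from 256 to 0.0507 in the authors' deposited table. No test was run on these genes, since the authors' deposited table holds no values per library.

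The unfolded protein and amino acid response rose as a group. Its list holds 38 names, with older and newer symbols of some genes, and 30 of its genes are in the authors' deposited table. All 30 were higher on the knockout side, with a median log2 fold change of 1.58. DDIT3, the stress transcription factor CHOP, went from 84.6 to 1493 in the authors' deposited table, the asparagine synthetase ASNS from 727 to 12878 and the cystine transporter SLC7A11 from 321 to 5330. The labelled reads, which are not independent of that table, moved alike, with 17 of 17 members higher in the polyclonal knockout and a median log2 change of 1.96. Targets of p53 were also mostly higher, 22 of 27 in the authors' deposited table, with a median of 1.46. GDF15, a stress-induced cytokine, went from 142 to 4244 in the authors' deposited table, EDA2R from 45.6 to 502 and SPATA18 from 57.7 to 554. MYC and its targets were higher in 24 of 31 cases in the authors' deposited table, with a median of 0.63, led by the complex I assembly factor NDUFAF4 (log2 1.77) and the ribosome biogenesis factors RRP12 (log2 1.33), NIP7 (log2 1.27) and NOP58 (log2 0.96). MYC itself, singled out after its value was seen because of its known link to FUBP1, was lower in the authors' deposited table (2873 to 2384, log2 -0.27). Among 10000 random lists of listed genes matched on mean expression, these 3 medians in the authors' deposited table stood at percentiles 100, 100 and 99.7. Genes not listed enter neither the counts nor the percentiles of any list.

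Cell cycle genes fell together: all 42 members in the authors' deposited table were lower on the knockout side, with a median log2 fold change of -1.81, below all 10000 matched random lists. The replication licensing factors MCM2 (1348 to 198) and MCM5 (1337 to 225), the transcription factor E2F1 (log2 -2.51) and the cyclin CCNE2 (424 to 84.2) changed most in the authors' deposited table. In the labelled reads 23 of 24 cell cycle members were lower in the polyclonal knockout, with a median of -1.35. DNA repair genes were lower in 35 of 52 cases in the authors' deposited table (median -0.65, percentile 1.63), among them RECQL4 (log2 -2.26), LIG1 (log2 -2.13), BRIP1 (log2 -2.01) and FANCB (log2 -1.99, but -0.16 in the labelled reads). Cholesterol synthesis fell in 18 of 19 listed genes (median -1.26, percentile 0) in the authors' deposited table, led by LSS (2906 to 807), IDI1 (3475 to 1003), MVD (550 to 187) and TM7SF2 (93.4 to 32.7). In the labelled reads 15 of 16 cholesterol genes were lower. Mitochondrially encoded transcripts, taken as a sign of RNA quality and prone to sharing reads with nuclear copies, were lower in 12 of 12 cases in the authors' deposited table (median -0.62, percentile 6.20), with MT-ND4L at log2 -1.14, MT-CYB at -0.99, MT-ND3 at -0.83 and MT-ND1 at -0.70.

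Most listed inflammatory cytokines, matrix genes and basal and mesenchymal markers were lower on the knockout side. The full lists hold 40 inflammatory, 41 matrix, 36 mesenchymal and 22 basal gene names, and genes not listed were left out. The authors' deposited table lists 27 inflammatory genes, 20 of them lower, with a median log2 fold change of -2.67 (percentile 0), and the neutrophil chemokines CXCL8 (1839 to 26.3), CXCL1 (2305 to 42.7) and CXCL5 (791 to 15.5) and the cytokine IL6 (332 to 13.2) fell most. Matrix and protease genes fell in 23 of 25 cases (median -1.90, percentile 0) in the authors' deposited table, including PLAT (log2 -3.92), MMP13 (log2 -3.01) and MMP2 (941 to 146). In the labelled reads 15 of 16 matrix genes were lower, with a median of -1.89. Mesenchymal markers were lower in 12 of 14 cases (median -1.66, percentile 0) in the authors' deposited table, among them TAGLN (1828 to 28.5), POSTN (514 to 10.6) and fibronectin, FN1 (19124 to 810). Basal mammary markers fell in 15 of 16 cases (median -1.15, percentile 0.12) in the authors' deposited table, with KRT17 going from 40213 to 1167, KRT14 from 62.5 to 3.77 and TP63 from 83.2 to 16.0. KRT14 and KRT17 share sequence with close copies, which makes their values uncertain. In the labelled reads 7 of 11 basal and 7 of 9 mesenchymal genes were lower (medians -1.21 and -0.35, the latter -0.96 and -0.94 in the count sets), while the 6 inflammatory genes with enough reads had a median of 0.03. The mesenchymal list holds all 3 fibroblast markers in the authors' deposited table, POSTN, FAP (4805 to 624) and DCN (89.0 to 30.1), which were among its lower genes.

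**Figure D1:**
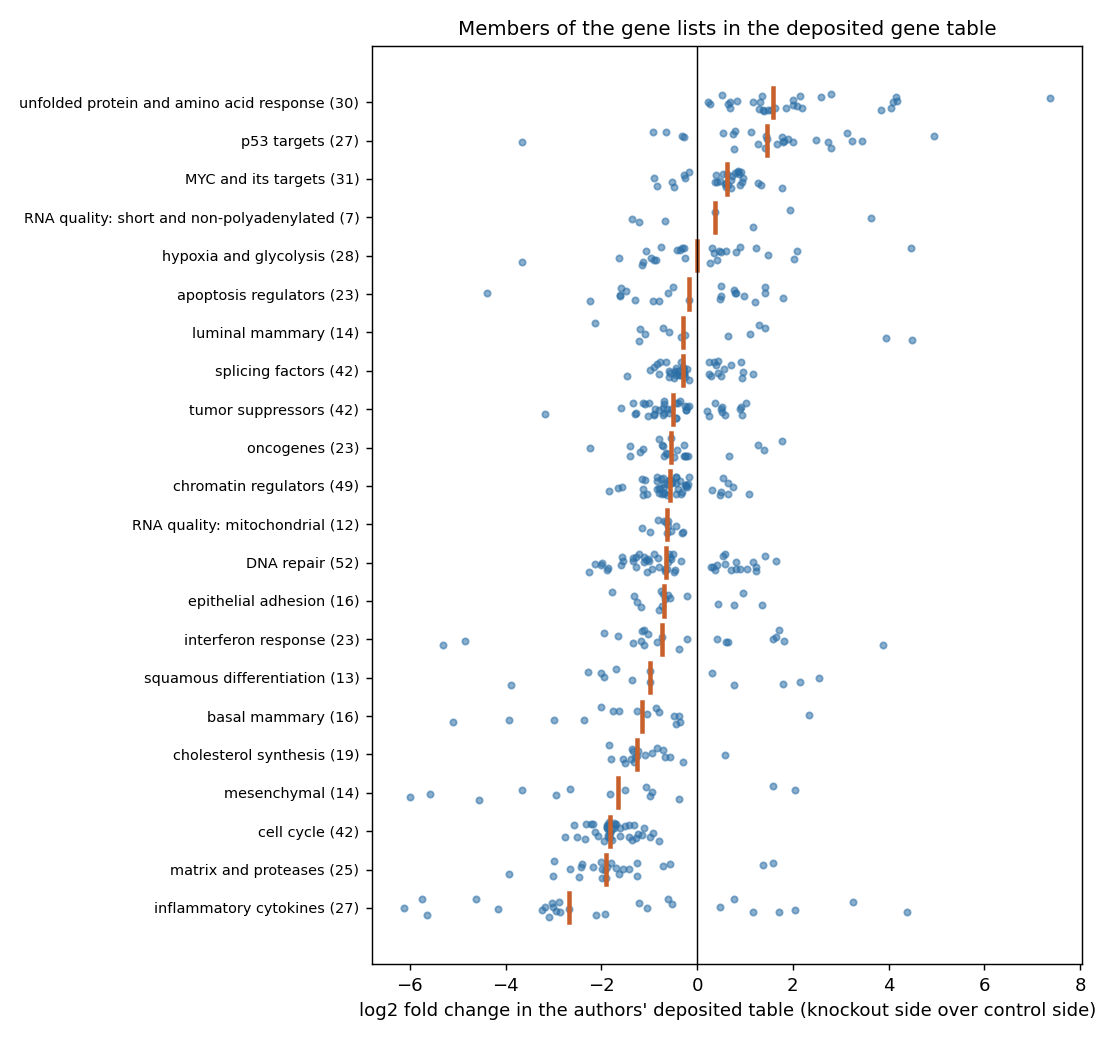
Log2 fold change of each list member in the authors' deposited table, knockout side over control side (x axis, 1 point per gene), for the lists with at least 5 listed genes (y axis, number of listed genes in brackets). Orange bars are medians over all listed members, and genes listed at 0 on a side are not drawn. The unfolded protein and amino acid response lies wholly above 0 (median 1.58) and the cell cycle list wholly below it (median -1.81).

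Listed chromatin regulators were mostly lower on the knockout side of the authors' deposited table, while tumor suppressors, oncogenes and splicing factors stood less apart from matched random lists. These lists hold 90 chromatin regulator, 76 tumor suppressor, 59 oncogene and 68 splicing factor names, and genes not listed were left out. Of 42 tumor suppressors, 31 were lower in the authors' deposited table (median log2 fold change -0.50, percentile 5.02), with TNFAIP3, an inhibitor of NF-kB signalling, at log2 -3.18, the mismatch repair gene MSH6 at -1.59 (-0.32 in the labelled reads) and CDKN2C at -1.29. Oncogenes were lower in 19 of 23 cases in the authors' deposited table (median -0.55, percentile 6.73), BCL2 at log2 -2.23 and CTNNB1 at -1.41 among them, whereas MDM2 (log2 1.77) and KLF4 (log2 1.40) were higher. Splicing factors went both ways, 14 higher and 28 lower in the authors' deposited table (median -0.30, percentile 28), with RBM39 (log2 1.17) and ZRANB2 (log2 0.96) higher and HNRNPUL1 (log2 -1.46) and SNRNP70 (log2 -0.98) lower. Chromatin regulators were lower in 41 of 49 cases in the authors' deposited table (median -0.57, percentile 0.915), HDAC5 (log2 -1.85), TET1 (log2 -1.65), KMT2B (log2 -1.57) and KDM2B (log2 -1.16) leading. The labelled reads were nearer to even, with 15 tumor suppressors higher and 26 lower (median -0.22), 10 and 12 oncogenes (median -0.30), 23 and 29 splicing factors (median -0.08) and 26 and 35 chromatin regulators (median -0.09).

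At the level of transcripts, the authors' deposited table lists 22637 isoforms, 9572 higher and 13065 lower on the knockout side. Coding transcripts were higher in 42.0% of 14867 cases, transcripts annotated for nonsense-mediated decay in 48.8% of 1784 and retained-intron transcripts in 42.2% of 2850, in the authors' deposited table. Of 5714 genes with several transcripts in the authors' deposited table, 2732 had transcripts in both directions. Zero means were frequent in the authors' deposited table, 2116 on the control side and 1468 on the knockout side, and transcripts of a gene share reads, so single transcripts are uncertain.

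Splicing differed between the control and the polyclonal knockout in all 5 event types. Of 17340 skipped exons with at least 20 reads in each library, 4191 in 2746 genes were called (Fisher's exact test on reads, Benjamini-Hochberg adjusted, and at least 10 percentage points), 2091 with higher and 2100 with lower inclusion in the knockout. Called events numbered 1264 of 3315 for mutually exclusive exons, 398 of 1276 for alternative 5' splice sites, 447 of 1373 for alternative 3' splice sites and 60 of 233 for retained introns. With a beta-binomial test that takes its overdispersion from the count sets, only 914 skipped exons, 41 mutually exclusive exons, 81 and 58 alternative 5' and 3' splice sites and 12 retained introns were called. Introns were retained less often in the knockout, 47 of 60 called introns (exact two-sided binomial test, p = 1.21e-05). At alternative 3' splice sites the longer exon was used less in 264 of 447 called events (exact binomial test, p = 0.000149). With the overdispersion of the count sets the share was 60.3% of 58 called events and did not pass (exact binomial test, p = 0.148). For skipped exons no lean passed the test at a difference of 10 points (exact binomial test, p = 0.902), and the direction turned with the threshold, from 52.99% lower at 5 points to 46.4% at 20 points (exact binomial tests, p = 5.95e-06 and 0.000524). With count set 1 alone 47.0% were lower (exact binomial test, p = 0.000594). Alternative 5' splice sites showed none that passed the test (209 of 398 lower, exact binomial test, p = 0.341). For mutually exclusive exons 677 of 1264 called events were lower (exact binomial test, p = 0.0123), a lean that did not pass with count set 2 alone, with both count sets apart or with either overdispersion, and turned at a difference of 20 points (exact binomial tests, p from 0.142 to 0.564). Events are not independent replicates. The 2 count sets of the polyclonal knockout differed from each other by the same criteria at 2248 skipped exons, those of the control at 1. When both count sets of the knockout had to lie at least 10 points beyond both of the control, 2294 skipped exons were called, 1482 higher (64.6%) and 812 lower, and 32 retained introns, 25 of them lower. Simulated unchanged libraries under this rule gave on average 53.3% or 63.6% higher skipped exons, depending on the noise assumed. In these simulations exons without skipping reads in the control could gain none, which limits their lower calls.

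**Figure D2:**
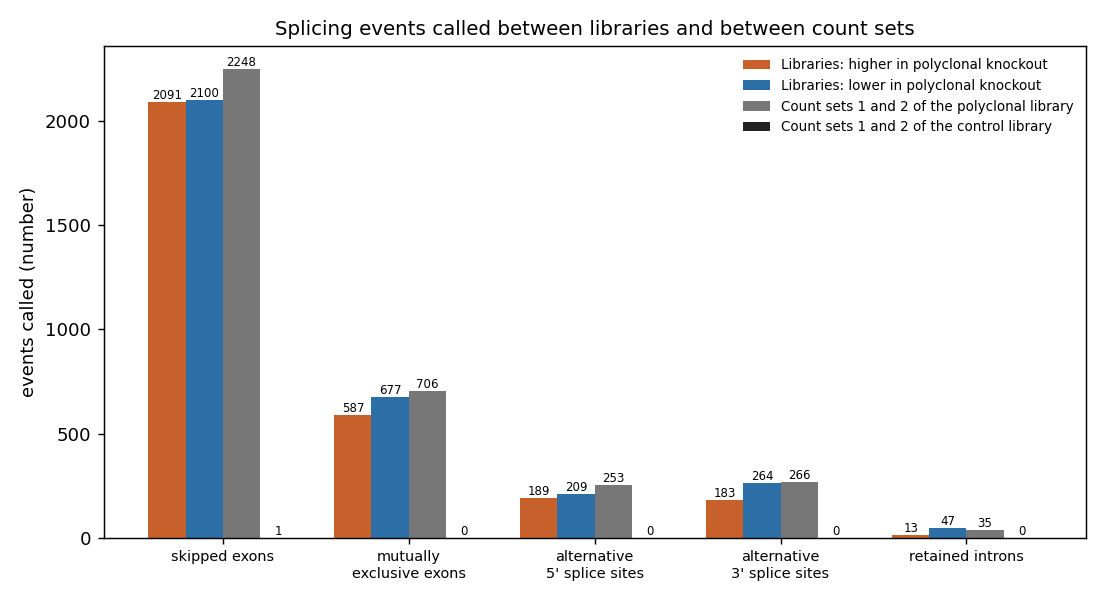
Number of called events (y axis) by event type (x axis). Orange and blue bars compare the control with the polyclonal knockout library by direction, grey and black bars compare the 2 count sets within the polyclonal and the control library. For skipped exons the bars stand at 2091, 2100, 2248 and 1.

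Among skipped exons with at least 50 reads in each library, the 10 with the largest differences in inclusion level, 1 per gene, ranged in size from EXTL3 (94.0 percentage points) to AHI1 (-80.9 percentage points). In EXTL3, a glycosyltransferase of heparan sulfate synthesis, inclusion of a coding exon at chromosome 8, 28715585 to 28718207, was 6.04% in the control (95% Wilson interval 4.56 to 7.96) and 100% in the polyclonal knockout (37.6 to 100, 63 reads). A coding exon of ZBTB16 (chromosome 11, 114156337 to 114156434) went from 11.8% to 100% (90.8 to 100), of C12orf49 (chromosome 12, 116723067 to 116723223) from 12.5% to 100% (86.6 to 100), of RFWD3 (chromosome 16, 74649132 to 74649202) from 17.8% to 100% (89.7 to 100), and of TMEM139 (chromosome 7, 143285941 to 143286202) from 5.67% to 93.1% (78.6 to 98.0). In the opposite direction, inclusion fell from 100% to 14.2% (10.3 to 19.3) for the coding exon of ZZZ3 at chromosome 1, 77631850 to 77633405, to 17.8% (11.7 to 26.1) for NCOA6 (chromosome 20, 34740363 to 34743341), to 17.9% (13.2 to 23.8) for the kinesin KIF21A (chromosome 12, 39318073 to 39318201) and to 19.1% (12.8 to 27.5) for an exon of AHI1 without annotated coding sequence (chromosome 6, 135495814 to 135495898). The lower bounds of the control values were 77.4% in ZZZ3, 41.5% in NCOA6, 90.3% in KIF21A and 90.5% in AHI1. All of these exons were apart in both count sets.

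Among the other event types, MARVELD2, a tight junction protein, changed its choice of mutually exclusive exons from 100% to 5.05% use of the exon at chromosome 5, 69419371 to 69420531, and TIAM1 from 10.7% to 91.3% of that at chromosome 21, 31276732 to 31276908. In ZNF75D the corresponding change was from 100% to 26.1%, but the count sets of the knockout stood at 0% and 77.4%. The longer form of the alternative 5' splice site fell from 100% to 1.89% in ZSCAN26 and from 96.7% to 8.69% in PIGA, and rose from 14.0% to 90.5% in ZNF302. At alternative 3' splice sites the longer form rose from 5.46% to 100% (63.9 to 100) in FAM122B. It rose from 5.61% to 74.8% (34.1 to 94.4) in the ubiquitin ligase subunit SKP2, where 1 of 64 knockout reads was a skipping read. It fell from 92.9% to 27.0% in IGF1R, where the forms differ by 3 bases (chromosome 15, 98929558 to 98929560). Retention of an intron fell from 100% to 30.2% in TMEM205, with 20.4% and 51.1% in the knockout count sets. It rose from 17.2% to 74.2% in STX16, with 100% and 58.0% in the knockout count sets. In SRSF10, a splicing factor, retention was 91.5% in the control and 29.9% in the knockout, whose count sets stood at 16.7% and 100%.

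The series title asks about splicing of tumor suppressors and oncogenes, and single exons in several of them changed by large amounts. A coding exon of BRCA2 (chromosome 13, 32344558 to 32344653, 96 bases) was included at 4.71% in the control (2.14 to 10.04, 68 reads) and 100% in the polyclonal knockout (77.5 to 100, 26 reads). In the chromatin remodeler PBRM1 a coding exon (chromosome 3, 52554724 to 52554879) went from 12.2% (8.28 to 17.5) to 93.6% (79.8 to 98.2). Coding exons of BCOR (24.5% to 100%, 84.4 to 100), APC (41.6% to 100%, 93.5 to 100) and CASP8 (45.6% to 100%, 92.2 to 100) had no skipping reads in the knockout, while another CASP8 exon (chromosome 2, 201272898 to 201272942) fell from 98.2% to 73.5%, with 90.6% and 60.8% in the count sets. A coding exon of BRCA1 at chromosome 17, 43106478 to 43106533, rose from 43.1% to 96.2%. Its longer form, 43106456 to 43106533, went both ways. Inclusion rose from 70.2% to 97.9% in an event and fell from 100% to 85.6% in another, with 100% and 75.9% in the count sets of the latter. The BRCA1 exon at 43095846 to 43095922 fell from 100% to 53.7%, with 18.0% and 94.8% in the count sets, and a KDM6A exon (chromosome X, 45010961 to 45011019) from 100% to 64.1%, with 100% and 38.6%. The longer form of an alternative 3' splice site fell from 94.0% to 44.7% in BRCA1 and from 64.8% to 28.2% in SMARCA4 (469 and 324 reads). In SPOP the use of a mutually exclusive exon rose from 42.4% to 78.4%.

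**Figure D3:**
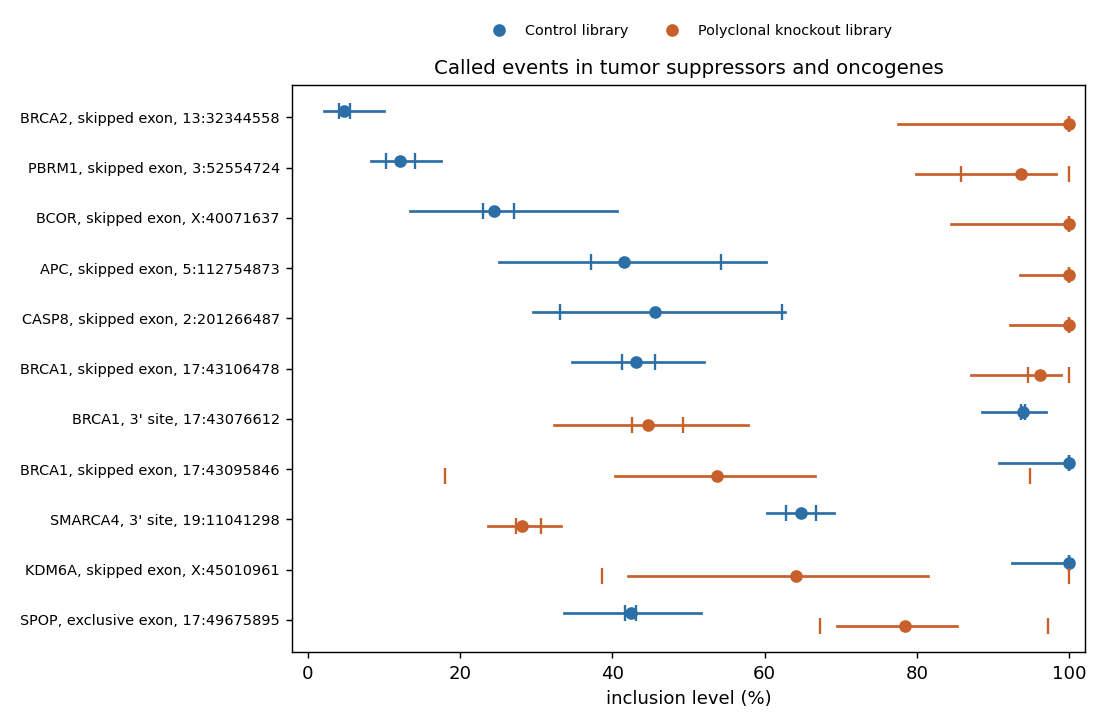
Inclusion level in percent (x axis) of called events with large differences in tumor suppressors and oncogenes (y axis: gene, event type, chromosome and start). Dots are library values with 95% Wilson intervals from counting error, and ticks are the 2 count sets of each library. The BRCA2 exon stands at 4.71% and 100%, and the ticks of the BRCA1 exon at 43095846 and of KDM6A lie far apart in the knockout.

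As groups, these lists did not stand out. Of 46 tumor suppressors with a tested skipped exon 22 had a called one, 47.8% against 41.9% of the other genes (odds ratio 1.27, 95% interval 0.717 to 2.26, two-sided Fisher's exact test across genes, p = 0.455, adjusted over 21 lists 0.780). For oncogenes 9 of 25 genes had a called exon (odds ratio 0.796, 95% interval 0.358 to 1.77, Fisher's exact test, p = 0.686, adjusted 0.780). The 22 tumor suppressors held 35 called skipped-exon events, 20 higher and 15 lower, and the 9 oncogenes 10, of which 8 were higher. Some exons count in several events, such as a BRCA1 exon that counts in both directions. With both count sets apart there were 18 such events in tumor suppressors, 15 higher and 3 lower, and 8 in oncogenes, all higher. Under this rule 64.6% of all 2294 called skipped exons were higher. It dropped 61.3% of lower and 29.1% of higher calls over all genes. Whether the 2 lists lean further towards higher inclusion than all called skipped exons was not tested. FUBP1 itself is in the tumor suppressor list and is among its lower events. Genes of the MYC list had called exons less often (3 of 28 genes, odds ratio 0.189, Fisher's exact test, adjusted p = 0.00908), as did interferon response genes (1 of 16, odds ratio 0.133, Fisher's exact test, adjusted p = 0.0383). Neither call held in a logistic model with the number of tested exons and the depth of each gene, although the odds ratios of 0.253 and 0.0947 stayed low. The MYC call was also lost with any event type and with both count sets apart (odds ratios 0.362 and 0.262, Fisher's exact test, adjusted p = 0.110 and 0.365) and held with the authors' FDR (0.185, adjusted p = 0.00821). The interferon call was lost with the authors' FDR and with both count sets apart (odds ratios 0.233 and 0.270, Fisher's exact test, adjusted p = 0.197 and 0.607) and held with any event type (0.189, adjusted p = 0.0308). DNA repair genes had called exons in 27 of 48 cases and splicing factors in 24 of 52 (Fisher's exact test, adjusted p = 0.388 and 0.780), and no other list passed (adjusted p from 0.609 to 1). In the logistic model the odds ratio of splicing factors moved from 1.19 to 2.59 (95% interval 1.38 to 4.84), without passing after adjustment. That of squamous genes moved from 3.05 to 10.6 (95% interval 1.54 to 72.8), of inflammatory genes from 1.78 to 5.17 and of basal genes from 1.64 to 3.72. None of them passed, and others fell, such as DNA repair from 1.78 to 1.09. Genes are not replicates, and these tests describe the 2 libraries.

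Genes with a called exon were listed as changed in expression slightly less often than others. Of 2633 genes with a called skipped exon 1462 (55.5%) stood in the authors' deposited table, against 2242 of 3680 genes (60.9%) without (odds ratio 0.801, 95% interval 0.724 to 0.886, two-sided Fisher's exact test across genes, p = 1.89e-05). A split was made at the median of labelled reads, control plus polyclonal, on the exon of a gene with the most inclusion reads. Among genes in the upper part the authors' deposited table held 63.4% and 64.6% of them (odds ratio 0.948, Fisher's exact test, p = 0.534).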

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

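The tests in this part were chosen after the result was seen. The 2 count sets of the polyclonal knockout differed from each other at 2248 skipped exons by the criteria used between libraries, against 1 between those of the control. The same held for mutually exclusive exons (706 against 0), alternative 5' splice sites (253 against 0), alternative 3' splice sites (266 against 0) and retained introns (35 against 0). In SRSF10 the retained intron stood at 16.7% and 100%, in ZNF75D the exon at 0% and 77.4%, and in BRCA1 the exon at 43095846 at 18.0% and 94.8%. The median difference between count sets was 3.36 percentage points in the polyclonal knockout and 0.107 in the control.

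Lower depth alone is argued against, since control count sets thinned to the depth of the polyclonal ones gave 2 such exons. Inclusion reads of exons of 1 gene at least 10000 bases apart shifted together only in part (Spearman's rho across 1190 genes 0.232, 0.0821 in the control). Expression of a whole gene that differs between count sets changes both forms alike and so largely leaves the inclusion level. This correlation of read counts therefore cannot decide what made the inclusion levels differ. The spread of inclusion reads over counting error rose from 6.51 (median 3.52) at 20 to 50 reads to 147 (median 44.1) at 10000 reads or more. This is a spread of read counts, not of inclusion levels. It also grows with depth where expression differs between the count sets. It therefore cannot decide whether few molecules behind the reads are a cause. At 20 to 50 reads the spread was larger than in the control (1.15), which likewise cannot tell few molecules from other sources. Whether the count sets are separate cultures, libraries or runs is not given in the sources used here and no biological explanation was tested.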

How the results depend on the processing

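Alternatives that use the count sets, and for directions also the smaller difference, the count minimum of 10 and the beta-binomial test, were chosen after the data were seen. The tests, thresholds, lists and other alternatives were chosen before the data were examined. No cause was tested for the changes given here beyond what each alternative removes by construction. Of 8015 genes in the authors' deposited table, 3984 had an absolute log2 fold change of at least 1, and a posterior probability of 0.99 removed none. At a difference of at least 0.2, called events numbered 2293 skipped exons, 564 mutually exclusive exons, 234 and 276 alternative 5' and 3' splice sites and 33 retained introns. With the overdispersion of the count sets they numbered 914, 41, 81, 58 and 12, with both count sets apart 2294, 741, 242, 267 and 32, and with an overdispersion of 0.01 mutually exclusive exons numbered 676.

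The share of skipped exons with lower inclusion, 50.1%, was 52.99% at a difference of 0.05 (exact binomial p = 5.95e-06), 46.4% at 0.2 (exact p = 0.000524), 49.8% at 10 counts, 49.7% and 49.5% with an overdispersion of 0.01 and of the count sets, 35.4% with both count sets apart, and 47.0% (exact p = 0.000594) and 49.6% in count sets 1 and 2. For mutually exclusive exons it was 51.2% and 41.5% with these overdispersions, 48.2% at 0.2, 52.8% with both count sets apart and 51.9% in count set 2, none past the threshold. With the overdispersion of the count sets, alternative 5' sites stood at 46.9% and 3' sites at 60.3% (exact p = 0.148). Retained introns kept their lean in all alternatives run (68.0% to 91.7% lower).

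The odds ratio of tumor suppressors turned to 0.928 and that of oncogenes to 1.05 in the logistic model, and of oncogenes to 1.13 with both count sets apart, none past the threshold. Other lists that turned, all without passing, were luminal (1.52), hypoxia (1.39), chromatin (0.851) and matrix genes (1.18) in the logistic model, mesenchymal (1.11) and apoptosis genes (0.952) with the authors' FDR, epithelial adhesion (0.683) and hypoxia (1.00) with any event type, and cell cycle (0.787), hypoxia (1.34) and stress response genes (1.01) with both count sets apart. With genes of a mean of at least 100 in the authors' deposited table, the squamous median was -0.98 at percentile 1.20 the apoptosis median turned to 0.49 and the interferon median was -0.37. Among genes above the median of labelled reads the overlap had an odds ratio of 0.948.

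Of 72 values for named events, 71 stayed called with the authors' FDR, 59 with an overdispersion of 0.01, 31 with that of the count sets and 51 with both count sets apart. In count set 2 alone 3 turned direction, the exon of EP300 (1.39 points), the KDM6A exon at 45062647 (23.8) and the SRSF10 intron (15.6). Labelled reads of 31 named genes gave a change within counting error of the deposited one in 6, moved it in 24 and turned its direction in 1, PECAM1 (log2 -0.17). Tests, normalizations, filters, pseudocounts and models that need values per library, and leaving out libraries, could not be run on genes, isoforms and lists. No paired analysis was possible because the labels give no replicate numbers shared between groups. At counting noise 30% of simulated differences of 15 points were found. Few exons were changed in that simulation, which made the adjustment stricter than in the data. This share is therefore not set by depth alone and is not the detection rate of the comparison.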

Other observations

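The tests on direction and introns in this part were chosen after the results were seen. Several lists fixed in advance went both ways. The luminal list holds 26 names, squamous 43, adhesion 31 and interferon 52, and genes not listed were left out of the counts. Among luminal markers 6 were higher and 8 lower in the authors' deposited table (median log2 -0.29, percentile 40.3, labelled median -1.07 over 7 members), with the secreted protein AGR2 going from 120 to 2654, KRT19 from 2.11 to 45.1 and KRT15 from 25208 to 66313, but CD24 from 52157 to 11872. Squamous differentiation genes were lower in 8 of 13 cases in the authors' deposited table (median -0.99, percentile 3.87), S100A8 (log2 -3.89) and PI3 (log2 -2.27) among them, whereas CSTA (log2 2.54) and KRT10 (log2 2.15) were higher. Epithelial adhesion genes were lower in 12 of 16 cases in the authors' deposited table (median -0.69, percentile 2.15), with CLDN1 at log2 -1.78, GRHL2 at -1.33, CLDN4 at -1.24 and the desmosomal cadherin DSG3 at 1.35, while the labelled reads of 18 members had a median of 0.04. Interferon response genes split 9 to 14 in the authors' deposited table (median -0.73, percentile 12.9, and -0.37 and 43.8 for genes with a mean of at least 100), with TRIM22 higher (log2 3.89, 2.66 in the labelled reads), OASL listed at 0 on the control side, and IFITM1 (281 to 6.86) and GBP2 (2127 to 73.5) lower. In the labelled reads 9 of 15 members of this list were higher (median 0.18), with medians of -0.02 and -0.23 in the count sets.

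Hypoxia and glycolysis genes split 14 to 14 in the authors' deposited table (percentile 61.7), with CA12 (log2 4.46), P4HA1 (log2 2.10) and the hexokinase HK2 (log2 2.03) higher and ENO2 (log2 -3.66) lower. Apoptosis regulators split 11 to 12 in the authors' deposited table (median -0.16, percentile 63.7, turning to 0.49 and 88.5 for genes with a mean of at least 100), the BH3-only gene PMAIP1 higher (log2 1.79) and the death ligand TNFSF10 (log2 -4.39) and CASP10 (log2 -1.61) lower. Short and non-polyadenylated RNAs split 4 to 3 in the authors' deposited table (median 0.37, percentile 65.2), with the histone genes HIST1H4H (log2 3.62) and HIST1H1C (log2 1.95) higher and SNORD3A (log2 -1.36) and HIST1H2BK (log2 -1.21) lower. Of the markers of other cell types, the endothelial KDR was lower (log2 -5.42) and PECAM1 higher (log2 1.11) on the knockout side of the authors' deposited table, though the labelled reads of PECAM1 had a log2 change of -0.17. Of immune markers, CD14 was higher (log2 1.31) and CD79A listed at 0 on the knockout side in the authors' deposited table.

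Skipped exons apart in both count sets were mostly higher in the knockout (64.6% of 2294), though calls on summed reads were even. Noise of the polyclonal count sets cannot be told apart from a real lean: simulated unchanged libraries reached at most 59.8% higher with a dispersion for each form and 67.8% with that of inclusion reads for both. These simulations gave on average 264 and 371 such exons, against 2294 observed. In them exons without skipping reads in the control could gain none, and the same dispersion was used at every depth. The totals therefore do not tell how many of the 2294 stem from noise. Of the 1288 lower calls lost, 64.0% had at least 90% of their skipping reads in 1 count set. Asking for both count sets removes such calls by construction, so this share cannot tell whether they account for the lean.

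A hypothesis is that FUBP1 matters most for exons behind long introns. The upstream intron had a median of 4480 bases for exons lower in the knockout and apart in both count sets, 3239 for those higher, and 3551 for 12151 exons without a call. Exons that differed only between the polyclonal count sets also had long upstream introns (median 4101.5), so a role of FUBP1 cannot be told apart from instability of such exons in this library, with 1 control and 1 polyclonal library to compare.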
